A study of Mus musculus with 11 samples.

How the data were processed

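Mate-pair sequencing joins the ends of long genomic fragments into a circle and reads both ends, so that a fragment across a rearrangement gives a pair of ends that map far apart or on different chromosomes. The series holds 11 mouse libraries. Per the labels, 5 came from neurons of the forebrain of CK-p25 mice after 2 weeks of induction by removal of doxycycline from the diet, and 6 from primary neuronal cultures. CK-p25 mice carry an inducible transgene for p25, the activator of CDK5, in forebrain neurons. The forebrain libraries are labelled NeuN-positive γH2AX-negative, all γH2AX-positive, Con, Step 1 and Step 2, with 1 library each; γH2AX marks chromatin around DNA double-strand breaks and NeuN is a neuronal nuclear protein. The labels do not say what Con, Step 1 and Step 2 stand for. The cultures received DMSO, or etoposide, a topoisomerase II inhibitor, at 5 µM for 2 h or 12 h with 36 h of recovery, with 2 libraries per group.

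Per the labels' protocols, fixed sorted nuclei were decrosslinked, and their DNA was tagmented to between 1 and 5 kb, circularised, sonicated and enriched for biotinylated junctions. The protocols name 2 kits for the final library step and read lengths of 75 or 40 bases, without saying which library had which. According to the submitters' processing notes, the reads of a pair were mapped apart from each other with Bowtie2 to mm10, duplicates were removed with SAMtools and positions were written with bedtools. Neither a tool version nor a mapping quality filter is stated. The deposited files list 1 mate pair per line, as chromosome, mm10 position and strand of each end, with no normalization by the authors; whether positions count from 0 or 1 is not stated.

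A pair was used when both ends lay on chromosomes 1 to 19 or X and outside 10 kb bins holding over 3 times the median of 812 ends. This left out 48 of 255830 bins with 0.154% of ends. Pairs with the same positions and strands at both ends were counted once per library, in either order of the ends. A filter at a mapping quality of 30 had been planned, but the files hold no mapping quality, so that filter and its alternatives were not run. Long-range pairs joined different chromosomes or positions over 20 kb apart; all others were short-range. Short-range pairs were split into outward-facing pairs (the mate-pair orientation), inward-facing pairs and same-strand pairs. Gene bodies were the start to end of 49554 genes of the reference annotation, which gives neither strand nor exons. Exons were therefore not analysed here, and the planned promoter class became positions within 1 kb of either gene end, with 5 kb as the alternative. An end in overlapping genes counted for each of them.

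For the cultures, long-range ends per gene and per 1 Mb window, and short-range ends per window as coverage, were fitted with limma voom (limma 3.58.1 in R 4.3.3), with all 6 libraries in a single fit, empirical Bayes variances and a Benjamini-Hochberg threshold of 0.05. Features needed at least 10 ends in at least 2 libraries. Values in CPM are counts of ends scaled to a common total. For fitted culture values that total is the long-range ends in tested genes, or in tested windows, after voom's addition of 0.5 to each count. It is all long-range ends for forebrain genes and for pooled lists; where CPM refer to used or short-range pairs, the text says so. Standard errors come from the fit. Shares were compared between culture groups by exact two-sided permutation tests, which with 2 against 2 libraries cannot give a p below 0.3333. The labels do not say whether replicates are separate cultures, so these p-values measure a spread between libraries that may be technical.

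Forebrain groups have 1 library each, so no test was made between them. Shares are given with exact Clopper-Pearson 95% intervals, and ratios with intervals from the exact conditional binomial distribution; both cover counting error only. A count of 0 was bounded with a floor of 3 counts over the group. In data simulated from the Step 1 and Con libraries with counting error only, 96.0% of such intervals for 2763 genes held the true ratio. In simulated counts for 2 h of etoposide against DMSO, limma recovered 2 of 67 genes changed 1.5-fold, 21 of 67 changed 2-fold and 46 of 66 changed 4-fold, with 1 false call, and made 0 calls when nothing had changed. These counts had a dispersion fixed at 0.005, not estimated from the libraries. Where real libraries vary more, recovery would be lower.

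The 13 gene lists were long neural genes, synaptic and neuronally expressed genes, activity-regulated genes, p53 and damage response genes, clustered protocadherins, clustered histones, olfactory and vomeronasal receptors, housekeeping genes, genes of other tissues, and markers of astrocytes, oligodendrocytes, microglia and vessels. In cultures, lists with at least 5 tested members were tested with camera (preset correlation 0.01, and the estimated one) and fry from limma; smaller lists were pooled. In the forebrain, a list's median was placed among 10000 random lists of equal size matched on count. The lists, main settings, comparisons and alternatives were fixed before the data were examined, apart from the additions named below.

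Named culture genes were up to 15 higher and 15 lower genes by absolute log2 fold change among those past the threshold with no overlap between groups; where fewer than 20 qualified, up to 3 list members with the most ends were named per list, up to 25. Named forebrain genes were the 10 highest and 10 lowest ratios among genes with at least 50 ends over both libraries; some genes that met this rule are not reported here. Windows followed the culture rule, and the 10 junctions with the most pairs were named. Other list members named in the text were chosen after their values were seen.

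A recurrent junction was a combination of 10 kb bins joined by at least 3 distinct long-range pairs in a library. Where pairs at recurrent junctions were left out, and for the percent of a gene's ends at them, the set was larger. It held the 11858 combinations joined by at least 3 pairs summed over all 11 libraries. Random pairing was estimated by shuffling the ends of interchromosomal pairs 5 times. Alternatives changed the distance limit, the denominator of culture shares (outward-facing pairs), duplicates, masked bins, normalization, count filter, groups fitted and replicates, and used short-range ends as an offset. Chosen after seeing the data were the class of pairs 100 kb to 10 Mb apart with its expectation from random pairing, counting pairs within 10 bases once, leaving out pairs at recurrent junctions, outward-facing pairs as denominator of forebrain shares, comparisons of forebrain libraries with a like pair orientation, and division of forebrain gene ratios by short-range ratios. Counting, exact tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.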

Results

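The libraries held between 5771541 and 16042105 deposited pairs. In the forebrain, 8266532 pairs were used for the NeuN-positive γH2AX-negative library, 10346674 for the all γH2AX-positive library, 8513650 for Con, 13952403 for Step 1 and 11971792 for Step 2. Among cultures, 6996915 and 5228351 pairs were used for DMSO, 5658693 and 5293471 for 2 h of etoposide, and 7722727 and 6424986 for 12 h. Identical pairs removed amounted to between 2.47% (all γH2AX-positive) and 14.9% (NeuN-positive γH2AX-negative) of pairs.

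The libraries fell into 2 types that the labels do not name. Inward-facing pairs within 1 kb made up 0.220% of the all γH2AX-positive library, 0.404% of Con and 0.289% and 0.268% of the 12 h etoposide libraries. The other libraries held more, from 1.46% in NeuN-positive γH2AX-negative nuclei to 13.1% in Step 1, 18.2% in Step 2, 32.5% and 35.8% in DMSO, and 39.5% and 18.7% after 2 h of etoposide. Short-range coverage moved with it: autosomal windows in the top 25% by gene content had 0.371 times (Con) to 1.01 times (12 h, replicate 2) the ends of gene-free windows in the first type, and 1.62 to 2.22 times in the second. Because all 12 h libraries are of the first type and all DMSO and 2 h libraries of the second, treatment for 12 h and library type cannot be told apart. The same holds for all γH2AX-positive against NeuN-positive γH2AX-negative nuclei and for both Step libraries against Con.

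**Figure D1:**
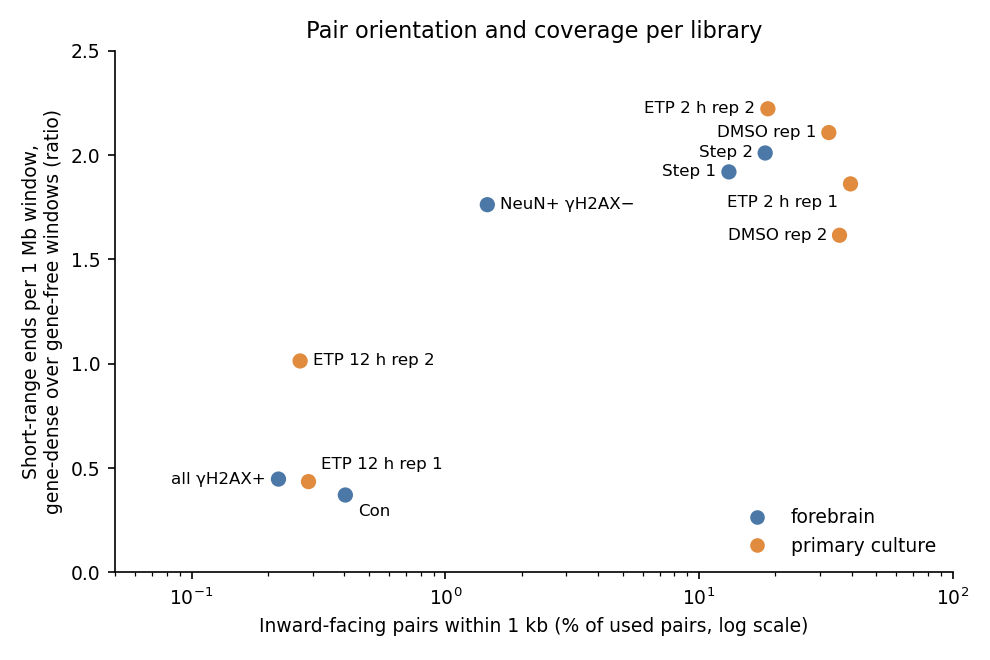
Each point is a library, with the percent of used pairs that face inward within 1 kb (log axis) against the ratio of short-range ends in gene-dense over gene-free 1 Mb windows. The all γH2AX-positive, Con and 12 h etoposide (ETP 12 h) libraries lie below 1% inward pairs, and the other libraries lie at 1.46% or more.

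The question behind the 2 h cultures is whether a short pulse of double-strand breaks leaves neurons with more joined distant ends. After 2 h of etoposide, 3.99% ± 0.0751 (SD, n = 2) of pairs were long-range, against 4.75% ± 1.56 in DMSO, a difference that over all used pairs lay within the spread between DMSO replicates (-0.755 percentage points, exact permutation p = 1, adjusted p = 1 over 9 tests). Interchromosomal pairs made up 3.59% ± 0.0692 and 4.26% ± 1.51 (difference -0.674, exact p = 1). Taken as a percent of outward-facing short-range pairs, which leaves out the inward-facing and same-strand pairs, long-range pairs stood at 6.41 ± 1.38 against 8.28 ± 2.498 (difference -1.87, exact p = 0.667). Interchromosomal pairs stood at 5.76 ± 1.24 against 7.43 ± 2.43 (-1.67, exact p = 0.667). Over all used pairs and without DMSO replicate 1, which held 5.85% long-range pairs against 3.64% in replicate 2, the differences turned to 0.350 and 0.393.

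Long neural genes, whose bodies offer the most sequence to break, were alike after 2 h of etoposide and DMSO at this depth. Cntnap2 (chromosome 6, 45060061 to 47301393), a neuronal adhesion gene, held 1699 ± 148 against 1673 ± 28.4 CPM (log2 fold change 0.02, SE 0.20). Lrp1b, on chromosome 2, differed by 0.11 on the log2 scale (SE 0.20) and Dmd, which encodes dystrophin, by 0.03 (SE 0.20). The activity-regulated genes Homer1, Crem and Rheb had log2 fold changes of 0.54 (SE 0.41), 0.25 (SE 0.48) and -0.16 (SE 0.54). Among glial markers, astrocytic Gpc5, Slc4a4 and Gli3 gave -0.11, -0.19 and 0.09, the microglial genes Dock2, Inpp5d and Apbb1ip -0.06, 0.45 and 0.76, and the oligodendrocyte genes Lhfpl3 and St18 0.03 and 0.19. The protocadherins Pcdha1, Pcdha2 and Pcdha3 gave -0.20, -0.19 and -0.21, the ciliary and retinal genes Dnah9, Rp1 and Dnah5 -0.08, 0.23 and 0.07, and the vomeronasal pseudogenes Vmn2r-ps16, Vmn2r-ps23 and Vmn2r-ps11 0.41, -0.05 and 0.42. Of the housekeeping genes, Sf3b1 gave 0.41 (SE 0.56) and Ywhaz -1.34 (SE 1.04, 5 against 20 ends).

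Over all genes, limma called 0 of 8362 for 2 h of etoposide against DMSO, with 144 at an unadjusted p under 0.05. It called 0 of 2580 windows on long-range ends (7 unadjusted) and 0 of 2573 on coverage (2 unadjusted), and the adjusted p of each gene named above was 1.00. No list held a called member, over all genes or adjusted over the list alone. The clustered protocadherins, cell-surface adhesion proteins encoded in tandem on chromosome 18, stood above other genes as a set (31 tested, median log2 fold change 0.31, camera adjusted p = 0.0265), and the adjusted p was 0.744 with an estimated correlation. Their gene bodies overlap, so 1 end counts for several members, and the set's call was absent with short-range ends as offset. Pooled long-range ends of the lists with under 5 tested genes were 206 ± 3.87 CPM in activity-regulated genes against 194 ± 25.8 in DMSO (exact p = 1, n = 2 per group). They were 42.4 ± 2.82 against 46.1 ± 20.3 in clustered histones (exact p = 1) and 129 ± 7.66 against 153 ± 21.3 in housekeeping genes (exact p = 0.3333).

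After 12 h of etoposide, windows over the immunoglobulin heavy chain locus and the Klra, Skint5 and Zfp987 genes held more long-range ends than after DMSO. The window at chromosome 12, 115000001 to 116000000, within the heavy chain locus Igh, held 6683 ± 108 CPM against 771 ± 238 (n = 2 each, log2 fold change 3.09, SE 0.25, adjusted p = 3.53e-05). A window on chromosome 6 from 130000001 over the Klra genes, which encode natural killer cell receptors, was higher by 1.92 (SE 0.27, adjusted p = 0.00137). On chromosome 4, the window of Skint5 and Skint6 from 113000001 was higher by 2.10 (SE 0.28, adjusted p = 0.00121). A zinc finger cluster with Zfp987, Zfp600 and Rex2, from 146000001 on chromosome 4, was higher by 2.24 (SE 0.23, adjusted p = 0.000205). On the lower side, the window with 54 coding genes including Abca7, Stk11 and Gpx4 (chromosome 10, from 80000001) held 204 ± 68.7 against 682 ± 55.8 CPM (-1.75, SE 0.24, adjusted p = 0.00121). The window with 50 coding genes on chromosome 17 from 25000001 fell by 1.56 on the log2 scale (SE 0.23, adjusted p = 0.00161).

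Among single genes, Klra9 (75 against 6 ends, log2 fold change 4.10, SE 0.84, adjusted p = 0.000113) and Klra8 (59 against 4 ends, adjusted p = 0.00364) rose. So did the interferon-inducible genes Ifi204 (3.19, SE 0.65, adjusted p = 0.000106), Ifi211 and Mndal. Within Igh, Gm30996 (3.58, SE 0.48, adjusted p = 7.09e-11), Gm30948 and Gm40900 rose, and elsewhere Rex2, Zfp534, Gm7281 and Gm46451. Klra10 held 59 against 3 ends (adjusted p = 0.0113), Gm5953 24 against 1 (adjusted p = 0.0493), and Gm18341 23 against 0, at least 8.63-fold higher (adjusted p = 0.0135). Of the culture ends in these 15 genes, between 18.5% (Gm5953) and 96.0% (Gm18341) lay at recurrent junctions. Short-range ends in the 13 of them with any in DMSO were 1.57 (Rex2) to 10.2 (Klra8) times those in DMSO. Among lower genes were Rxra, a retinoid receptor (-3.28, SE 0.79, adjusted p = 0.00211), and Itpr3, an intracellular calcium channel (-2.50, SE 0.54, adjusted p = 0.000298). Lower too were Ccdc85c (-2.24, SE 0.47, adjusted p = 0.000182) and Smad3, a transducer of TGF-beta signals (-2.20, SE 0.45, adjusted p = 0.000113). Gpr55, Myo15, Csf2rb2, Ssh1, Itgae, Rbm19, Unc5b, Cbfa2t3 and Triobp also fell, Mast3 held 1 against 35 ends, and Fcho1 0 against 30, at least 8.88-fold lower. Short-range ends in the 15 lower genes were 0.0863 (Ccdc85c) to 0.461 (Gpr55) times those in DMSO.

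In all, 252 genes were higher and 275 lower among 8362, around a median log2 fold change of -0.22 over all genes. Of those called, 512 had no overlap between groups. Chance gives that 1 time in 3 for 2 against 2 libraries, but only for genes not selected on the same values. The called genes were so selected, and the 512 add no support to the calls. Quantile normalization split the calls into 387 higher and 234 lower, and short-range ends as offset into 583 and 283, while no filter on counts gave 137 and 67. The balance tipped the other way with limma-trend (144 higher, 291 lower) and with a minimum of 30 ends (107 and 257). Without DMSO replicate 1 the count was 20 (18 higher, 2 lower), and without 2 h replicate 2 it was 351 (173 and 178). Without 12 h replicate 1 it was 311, with 248 higher and 63 lower, so that the balance of directions turned. Among windows, 186 were higher and 454 lower of 2580 (413 and 545 with the offset). Their total was 184 without DMSO replicate 1, 1336 without 12 h replicate 2, 399 without 2 h replicate 1 and 407 without 2 h replicate 2. Coverage changed in the same direction in 451 of the 454 lower windows, with a median short-range log2 fold change of -1.29, and in 170 of 179 higher windows with a coverage value, with a median of 0.84.

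**Figure D2:**
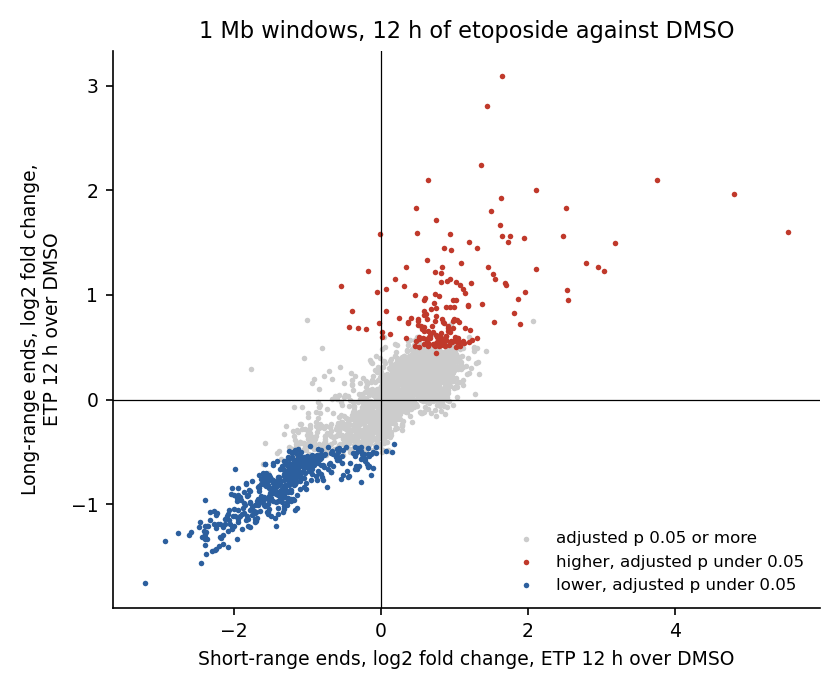
Each point is a 1 Mb window, with its log2 fold change in short-range ends (x axis) and in long-range ends (y axis) for 12 h of etoposide (ETP 12 h) over DMSO, n = 2 libraries each; red and blue mark windows past an adjusted p of 0.05 on long-range ends. Windows with fewer long-range ends lie almost all where short-range ends were also fewer, 451 of 454.

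Coverage itself was higher in 45 windows and lower in 2 of 2573. The secretoglobin cluster on chromosome 7 from 32000001 (log2 fold change 5.53, SE 0.46, adjusted p = 0.0123) and the Skint5 and Skint6 window (3.76, SE 0.15, adjusted p = 0.00119) gained most, followed by X-linked windows with Slx and Btbd35f genes. The Gria1 window on chromosome 11 fell by 1.08 (SE 0.15, adjusted p = 0.0389) and the Dscam window on chromosome 16 fell by 0.61 (SE 0.09, adjusted p = 0.0469). With quantile normalization the coverage calls split into 561 higher and 565 lower. Leaving out a library gave 0 (DMSO replicate 1), 3 (DMSO replicate 2), 2063 (12 h replicate 1; 1316 higher and 747 lower), 2253 (12 h replicate 2; 1210 and 1043) and 20 (either 2 h replicate).

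Of 50 long neural genes, 2 rose after 12 h against DMSO: Sgcz (log2 fold change 0.83, SE 0.21, adjusted p = 0.00326) and Mdga2 (0.71, SE 0.22, adjusted p = 0.0288), the same number adjusted over the list alone. The list's median was 0.22 (camera adjusted p = 0.000453), which turned to -0.46 with short-range ends as offset, and the adjusted p was 0.979 with an estimated correlation. The 12 h replicates lay on either side of the other libraries: their pooled long-range ends in these genes were 25944 and 16427 CPM, against 18723 and 19239 in DMSO and 19182 and 18495 after 2 h (exact p = 1 against either). Of 66 olfactory and vomeronasal receptors, 10 rose (11 adjusted over the list alone), such as Vmn2r-ps16 (2.17, SE 0.24, adjusted p = 1.79e-16) and Olfr183 (1.34, SE 0.33, adjusted p = 0.00279). Their median of 0.47 turned to -0.91 with the offset, and the camera adjusted p of 2.28e-09 became an adjusted p of 0.693 with an estimated correlation. Pooled over the whole list, receptors held 4652 and 4488 CPM after 12 h. The γH2AX-positive (4094) and Con (3858) forebrain libraries, of the same library type and without etoposide, also lay above every other library (2582 to 3501). Among 41 synaptic genes, 4 fell, over all genes and adjusted over the list alone, although the list's median of -0.37 turned to 0.32 with the offset. They were the calcium channel gene Cacna1a (-1.06, SE 0.27, adjusted p = 0.00364), Rbfox3, which encodes NeuN (-0.90, SE 0.25, adjusted p = 0.0118), and the synaptic scaffold genes Bsn and Shank2. The myelin gene Mbp fell (-1.45, SE 0.41, adjusted p = 0.0122), as 1 of 11 oligodendrocyte genes by either adjustment, in a list whose median was 0.13 and mean -0.22. Vascular genes had 0 of 11 past the threshold (2 lower adjusted over the list alone, median -0.63) and microglial genes 0 of 9 (1 lower adjusted over the list alone, median -0.06). No member of the astrocyte (median -0.06), protocadherin (-0.23), other-tissue (-0.16) or p53 and damage response (-0.02) lists passed, over all genes or adjusted over the list alone. Pooled ends were 135 ± 26.8 against 194 ± 25.8 CPM in activity-regulated genes (exact p = 0.3333, n = 2 per group). They were 29.4 ± 4.72 against 46.1 ± 20.3 in clustered histones (exact p = 0.667) and 97.0 ± 10 against 153 ± 21.3 in housekeeping genes (exact p = 0.3333).

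The share of long-range pairs was 3.77% ± 0.0534 after 12 h of etoposide (n = 2), which over all used pairs lay within the spread of DMSO at 4.75% ± 1.56 (difference -0.977, exact p = 1). Interchromosomal pairs made up 3.31% ± 0.0457 (difference -0.951, exact p = 1). Without DMSO replicate 1 the differences were 0.129 and 0.116. As a percent of outward-facing pairs the groups did not overlap: long-range pairs were 3.96 ± 0.0530 against 8.28 ± 2.498 in DMSO (difference -4.31) and interchromosomal pairs 3.48 ± 0.0452 against 7.43 ± 2.43 (-3.95), both exact p = 0.3333, the lowest possible. Pairs 100 kb to 10 Mb apart on 1 chromosome reached 2065 ± 94.0 CPM of used pairs, against 973 ± 72.4 in DMSO and 916 ± 8.47 after 2 h, 2.12 and 2.25 times as many (exact p = 0.3333 for each, the lowest possible). Outside recurrent junctions they stood at 942 ± 10.7 CPM after 12 h and 619 ± 98.0 in DMSO, 1.52 times as many. As a percent of outward-facing pairs they were 0.217 ± 0.00971 after 12 h, 0.170 ± 0.00774 in DMSO and 0.147 ± 0.0330 after 2 h. Each of these limits was applied alone. Outside recurrent junctions the libraries held 949 and 934 CPM after 12 h and 688 and 550 in DMSO. Outward-facing pairs made up 95.1% and 95.2% of used pairs after 12 h but 58.3% and 55.9% in DMSO. With both limits at once, the 12 h libraries would therefore not lie above DMSO replicate 1.

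**Figure D3:**
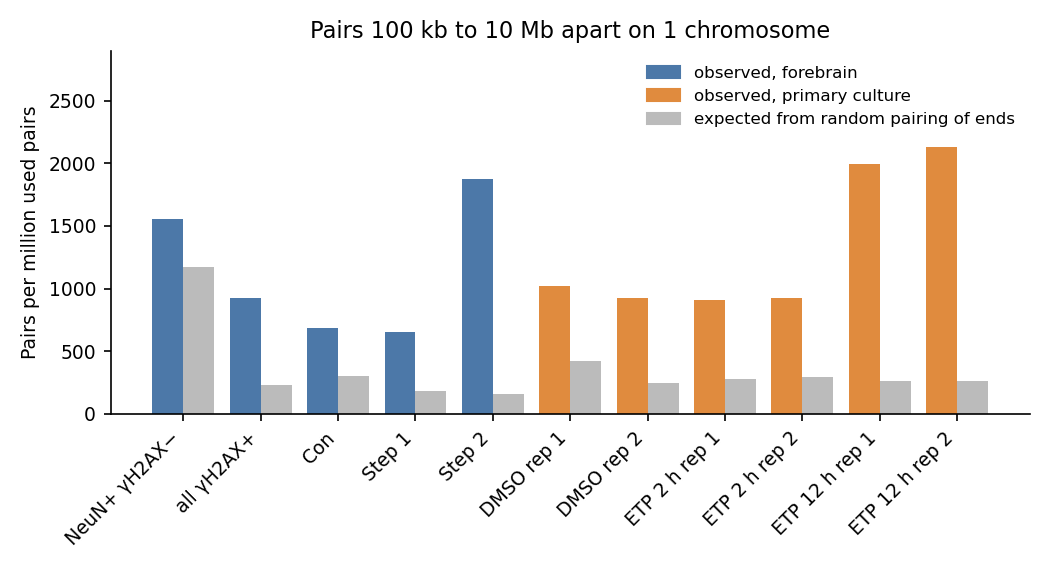
Bars give, for each library, pairs 100 kb to 10 Mb apart on 1 chromosome in CPM of used pairs, with observed values in colour and the expectation from random pairing of ends in grey. The Step 2 library (1876) and the 12 h etoposide libraries (1998 and 2131) stand at the top, with expectations of 156, 259 and 261.

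Between 12 h and 2 h of etoposide, the question is whether longer exposure changed where ends were joined. The same heavy chain locus stood out: Igh (chromosome 12, 113258768 to 116009954) held 28440 ± 943 CPM after 12 h and 4947 ± 540 after 2 h (n = 2, log2 fold change 2.53, SE 0.16, adjusted p = 8.98e-50). Of its culture ends 56.0% lay at recurrent junctions, and its short-range ends after 12 h were 2.01 times those after 2 h. Gm30996 (3.97, SE 0.96, adjusted p = 0.00315), Gm40900, Gm30948 and Gm40899 within it rose too. So did Klra9 (2.83, SE 0.77, adjusted p = 0.0109), Klra10, the zinc finger genes Rex2, Zfp991 and Zfp980 (2.53, SE 0.43, adjusted p = 2.18e-06), the splicing factor gene Srsf10, and Gm42346, Gm38997, Gm7281 and Gm7827. Lower were Rxra (-2.89, SE 0.80, adjusted p = 0.0136) and Kdm4b, a histone demethylase gene (-2.63, SE 0.65, adjusted p = 0.00389), together with Fam53b (-2.47, SE 0.54, adjusted p = 0.000727), Rap1gap, Mlxipl, Synpo, Csf2rb2, Tmem104, Rbm19, Flrt1, Unc5b, Cbfa2t3 and Myo15. Atp13a2, a lysosomal transporter gene, held 0 against 21 ends, at least 8.54-fold lower, and Ube2g2 0 against 17, at least 6.91-fold lower. Short-range ends in the higher genes other than Rex2, which had none after 2 h, were 1.001 (Gm40899) to 13.1 (Klra9) times those after 2 h, and those in the lower genes 0.0864 (Rbm19) to 0.359 (Csf2rb2) times.

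In total 135 genes were higher and 248 lower between 12 h and 2 h, around a median of -0.20 over all genes. Of these, 381 were free of overlap between groups, again after selection on the same values. The split was 148 and 171 under quantile normalization 591 and 356 with short-range ends as offset, 151 and 387 with limma-trend, 70 and 229 with a minimum of 30 ends, and 59 and 52 with no filter on counts. Without 12 h replicate 1 the balance turned to 143 higher and 35 lower, and without 2 h replicate 2 to 26 and 14. Without 12 h replicate 2 the split was 261 and 331, and without 2 h replicate 1 it was 36 and 89. For windows, 168 were higher and 498 lower (480 and 656 with the offset). That total was 1404 without 12 h replicate 2, 310 without 2 h replicate 1 and 2 without 2 h replicate 2, both higher. The window of 54 coding genes on chromosome 10 fell by 1.80 (SE 0.23, adjusted p = 0.00123) and that on chromosome 12 from 115000001 rose by 3.13 (SE 0.24, adjusted p = 2.26e-05). Coverage was higher in 95 windows and lower in 18 (524 and 571 under quantile normalization). The total moved to 8 and 2 without DMSO replicate 1 or 2, 2081 and 2232 without 12 h replicate 1 or 2, and 2 without either 2 h replicate. The long-range share differed by -0.221 percentage points and the interchromosomal share by -0.277, both exact p = 0.3333, the lowest possible, and adjusted p = 0.75. As a percent of outward-facing pairs the differences were -2.44 and -2.28, again with an exact p of 0.3333.

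Among the lists between 12 h and 2 h, 3 olfactory and vomeronasal receptors rose (6 adjusted over the list alone; median 0.39, camera adjusted p = 4.01e-06) and 1 long neural gene, Sgcz, rose (0 adjusted over the list alone; median 0.21, camera adjusted p = 5.31e-05). Both set calls had an adjusted p of 0.875 with an estimated correlation. Cacna1a (-1.15, SE 0.27, adjusted p = 0.0023) and Rbfox3 (-0.86, SE 0.26, adjusted p = 0.0276) fell among 41 synaptic genes (2 adjusted over the list alone). Mbp fell among oligodendrocyte genes (1 adjusted over the list alone). Of the genes of other tissues, Ryr1, which encodes a muscle calcium channel, fell (-1.39, SE 0.35, adjusted p = 0.0043; 4 adjusted over the list alone). Median log2 fold changes of the remaining lists were 0.05 for astrocytes, -0.63 for protocadherins, 0.12 for microglia, -0.11 for p53 and damage response genes and -0.56 for vessels, with 0 members past the threshold over all genes or adjusted over the list alone.

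In the forebrain, NeuN-positive γH2AX-negative nuclei had the highest share of long-range pairs, 15.8% (15.8 to 15.9), 14.9% of pairs being interchromosomal. All γH2AX-positive nuclei, those with the mark of double-strand breaks, had 3.15% (3.14 to 3.16), a ratio of 0.199 (0.198 to 0.1998). As a percent of outward-facing pairs the values were 19.6 and 3.29, a ratio of 0.167 (0.167 to 0.168). Before filtering, 166 of the 351 pairs with a mitochondrial end in the γH2AX-negative library had their other end on a nuclear chromosome. The counts were 14 of 222 in γH2AX-positive nuclei, 14 of 139 in Con, 14 of 202 in Step 1 and 6 of 179 in Step 2. In the γH2AX-negative library, pairs on 1 chromosome 1 to 10 Mb apart were 1.11 times the expectation from random pairing, and those over 10 Mb apart 1.03 times. The other forebrain libraries held 1.38 (Con) to 5.46 (Step 2) times and 1.04 (Con) to 1.66 (Step 2) times. At these distances the γH2AX-negative pairs were thus close to what random joining of ends would give. Whether such joining took place during preparation and raised the γH2AX-negative share was not tested. Relative to all long-range ends (CPM), the genes with the highest ratios of γH2AX-positive to γH2AX-negative nuclei were Gm13212 (chromosome 4, 145585172 to 145625343) at 9.33 times (6.93 to 12.7), Gm42346 at 9.07 times (5.86 to 14.3) and Sirpb1c at 6.57 times (4.45 to 9.79). They were followed by Vmn2r88, Zfp990, Rex2, Gm32584, Zfp984, Zfp980 and Vmn2r117 at 5.54 to 6.55 times. In these 10 genes 32.0% (Vmn2r117) to 68.2% (Gm32584) of the ends lay at recurrent junctions, and short-range ratios were 0.625 (Rex2) to 3.49 (Zfp990). Lowest were genes such as Baiap2 (chromosome 11, 119939916 to 120006782; 1 against 87 ends, ratio 0.0461, interval 0.00116 to 0.264), which organises actin at synapses, and Tbc1d16 (2 against 114 ends, 0.0704, 0.00843 to 0.260). Ctbp1, a transcriptional corepressor gene, had 0 against 50 ends (exact interval of the ratio up to 0.307, at least 4.15-fold lower at the floor of 3 counts). Pmepa1, Kif21b, Akna, Gm38845, Ccdc40, Cep250 and Ero1b had 1 end each against 54 to 70. Short-range ratios were also low in all 10 of these lower genes, and all 10 kept their direction after division by them.

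Olfactory and vomeronasal receptors had a median log2 ratio of 0.47 between γH2AX-positive and γH2AX-negative nuclei (percentile 100 of the random lists) and long neural genes 0.16 (percentile 99.3), while synaptic genes (-0.38, percentile 0.77) and protocadherins (-0.47, percentile 0.73) were low. After division by short-range ratios, long neural genes (-0.82) and receptors (-0.32) turned to percentiles of 0 and 0.03, and protocadherins to 99.2. Across 7861 genes, which are not independent replicates, long-range and short-range log2 ratios had a Pearson r of 0.710. Set against Con, a library of the same type, the γH2AX-positive share was 0.780 times (0.776 to 0.784), and 0.768 times (0.764 to 0.771) over outward-facing pairs.

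**Figure D4:**
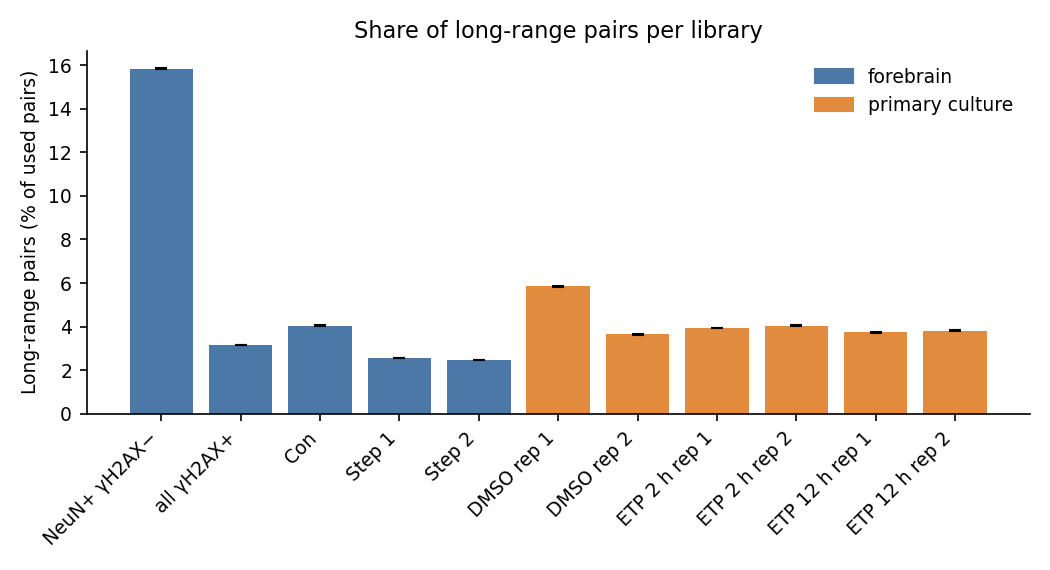
Bars give the percent of used pairs that are long-range in each library, and whiskers the exact 95% interval, which covers counting error only. The NeuN-positive γH2AX-negative forebrain library stands at 15.8%, and the others lie between 2.45% (Step 2) and 5.85% (DMSO replicate 1).

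The Step 1 library held 2.55% long-range pairs (2.54 to 2.56) and Con 4.04% (4.03 to 4.05), a ratio of 0.631 (0.628 to 0.634), or 0.844 (0.840 to 0.848) over outward-facing pairs. Relative to Con, Smo, the Hedgehog signal transducer gene (chromosome 6, 29735497 to 29761366), held 11.4 times the CPM in Step 1 (130 against 11 ends, 6.18 to 23.5), the non-coding gene 2700054A10Rik 9.12 times (6.25 to 13.8) and Cdk18 8.22 times (3.53 to 23.4). Gm51498, Gm2048, Gm41466, Gm20590, Zc3h7a, Ccnd3 and Gm36876 lay between 3.75 and 10.2 times. Skap2 (0.281, 0.150 to 0.498), Zfp951, the titin gene Ttn (25 against 81 ends, 0.298, 0.183 to 0.472), Gm32584, Mdfic, Mid2, Tbl1x, Gm29183 and Rab27b (0.394, 0.228 to 0.658) were lowest. In Smo, 73.8% of these ends lay at recurrent junctions and short-range ends were 5.71 times those of Con. After division by short-range ratios, 7 of the 10 higher and 9 of the 10 lower genes kept their direction; Cdk18, with 15.3 times the short-range ends of Con, turned to a log2 ratio of -0.97, Gm2048 to -1.30, Ccnd3 to -0.71 and Gm32584 to 0.22. Long neural genes had a median of -0.37 (percentile 0.83, and 96.4 after division by short-range ratios) and protocadherins 0.18 (percentile 98.3, then 32.8); r with short-range ratios was 0.546 across 2763 genes.

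In the Step 2 library, 2.45% of pairs were long-range (2.45 to 2.46), 0.607 times Con (0.604 to 0.610), or 0.959 times (0.954 to 0.963) over outward-facing pairs. Smo (11.3 times, 6.06 to 23.3) and 2700054A10Rik (10.6 times, 7.27 to 16.0) again held the highest ratios to Con, with 70.1% and 72.2% of their ends at recurrent junctions, followed by Gm2048, Gm20590, Msi1, a neural RNA-binding protein gene (5.22 times, 2.68 to 11.1), Gm36134, Gm16090, Galnt10, Zc3h7a and Acacb (4.15 times, 2.08 to 8.99). The lowest were Gm9733 (0.286, 0.128 to 0.580), Gm40159, 5430437J10Rik, Tbl1x, Ncoa7, Skap2, Lcorl, Zfp990, Gm13219 and Hnf4g (0.379, 0.223 to 0.620). Long neural genes had a median of -0.41 (percentile 5.55) and receptors -0.39 (percentile 5.81), which became 96.4 and 99.4 after division by short-range ratios; r with short-range ratios was 0.677 across 2526 genes. After that division, 5 of the 10 higher and 9 of the 10 lower genes kept their direction. The log2 ratios of Gm2048 (-1.003), Msi1 (-0.77), Gm36134 (-0.80), Galnt10 (-0.79), Acacb (-1.36) and Hnf4g (0.73) turned.

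Step 2 and Step 1 are of the same library type, and their long-range and short-range log2 ratios were nearly unrelated across 2653 genes (r 0.0895). The long-range share of Step 2 was 0.963 times that of Step 1 (0.958 to 0.967), but 1.14 times (1.13 to 1.14) over outward-facing pairs, so its direction depends on the denominator. Eps15, an endocytosis gene (36 against 16 ends, 2.72 times, 1.47 to 5.26), Myom1 (2.37 times, 1.44 to 4.01), Rcor1, Evl, LOC115488208, Galnt10, Adgrf5, Heg1 and Fam126a (2.06 times, 1.15 to 3.77) had the highest ratios. 5430437J10Rik (0.382, 0.182 to 0.747), the ion channel gene Trpc6 (0.420, 0.227 to 0.742), Arhgef38, Wnk3, Rapgef5, Myo3a (52 against 133 ends, 0.473, 0.337 to 0.657), Hnf4g, Ccdc57, Gm21154 and Csrnp3 had the lowest. With 2653 genes, intervals that exclude 1 are also met by chance at these counts. Clustered protocadherins had a median log2 ratio of -0.33 over 23 genes (percentile 0.01, and 0.46 after division by short-range ratios); their overlapping gene bodies share ends, which random lists seldom do. Long neural genes stood at -0.004 (percentile 85.3).

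The clearest difference between Step 2 and Step 1 lay in pairs 100 kb to 10 Mb apart, which made up 0.188% (0.185 to 0.190) of Step 2 and 0.0650% (0.0637 to 0.0664) of Step 1, a ratio of 2.89 (2.82 to 2.96), or 3.40 (3.32 to 3.49) over outward-facing pairs. Con held 0.0683% (0.0666 to 0.0701), a ratio of 2.75 (2.67 to 2.83) for Step 2. Observed pairs exceeded random pairing 12 times in Step 2, 3.59 times in Step 1, 2.26 times in Con, 4.07 times in γH2AX-positive and 1.33 times in γH2AX-negative nuclei.

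By location, long-range ends were scarcer in gene bodies than short-range ends of the same library in DMSO (ratio 0.872 ± 0.0107, n = 2) and after 2 h of etoposide (0.859 ± 0.000389), and stood at 0.949 ± 0.0683 after 12 h. Within 1 kb of a gene end the ratios were 0.876 ± 0.00206, 0.863 ± 0.0187 and 1.12 ± 0.137 in the same order. They were, in coding genes under 20 kb, 0.813 ± 0.00424, 0.779 ± 0.0129 and 1.17 ± 0.219, and in coding genes over 300 kb 0.889 ± 0.0319, 0.890 ± 0.000777 and 0.820 ± 0.000315. Every exact permutation p over these 21 tests was 0.3333 or more, with adjusted p of at least 0.438. The share of long-range ends in gene bodies was itself lower after 12 h (44.4% and 43.7%) than in DMSO (49.9% and 47.2%). The share of short-range ends fell further, from 56.7% and 54.6% to 44.5% and 48.6%. In γH2AX-positive nuclei and Con, of the 12 h library type and without etoposide, the gene-body ratios were 0.991 and 1.05. Within 1 kb of a gene end they were 1.13 and 1.18, so these ratios after 12 h cannot be told apart from library type.

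Recurrent junctions numbered 4375, of which 1674 were seen in more than 1 library. The most frequent joined neighbouring members of duplicated families: A530032D15Rik (chromosome 1, 85080001 to 85090000) to Sp140 (85620001 to 85630000) with 403 pairs in 11 libraries, and Gm38510 to Sp110 and Sp140 with 216. On chromosome 4, Zfp978 was joined to Zfp982 by 157 pairs, and the bin at 145400001 to Gm13212 by 212 and to Gm13226 by 141. A junction on chromosome 17 between 13580001 and Gm41530 had 270 pairs. Others joined different chromosomes: Gm20590 on 13 to 2700054A10Rik on 17 with 192, Gm52725 on 4 to Cldn34d on X with 176, Gm40034 on 2 to a bin on 3 at 8240001 with 160, and Smo on 6 to 2700054A10Rik with 145. The 12 h etoposide libraries held 1886 and 1833 recurrent junctions (3.45% and 3.96% of long-range pairs) and every other library between 367 and 693. That order holds at 3 pairs or more: at 2 or more, NeuN-positive γH2AX-negative nuclei held 21196, of which 20678 were in that library only, against 4800 and 4988 after 12 h. At 3 pairs or more, the γH2AX-positive and Con forebrain libraries, of the same type as the 12 h libraries, held 467 and 394. No DMSO or 2 h culture is of that type, so why the 12 h libraries held more was not tested.

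**Figure D5:**
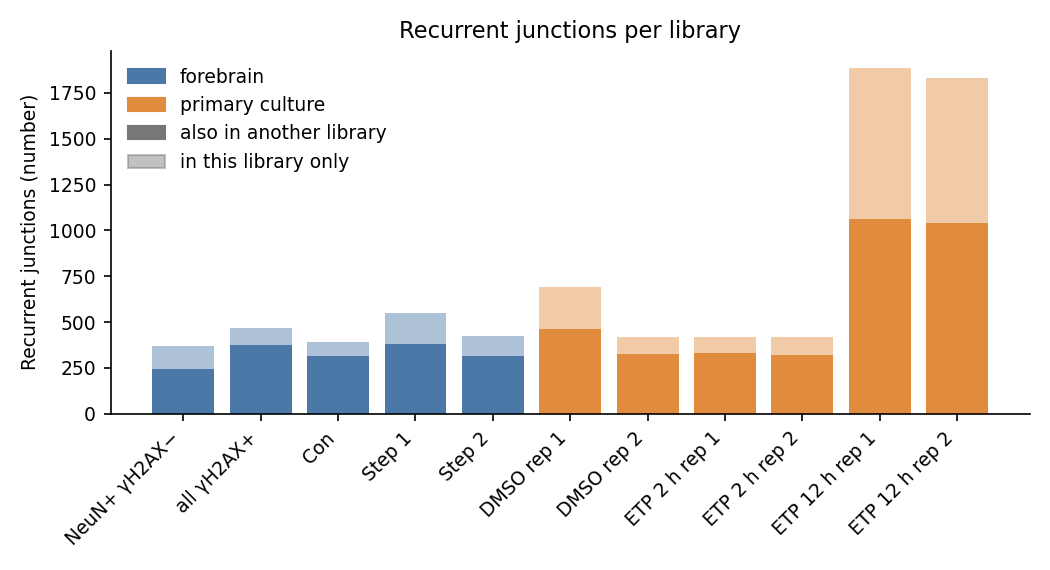
Bars give the number of recurrent junctions per library, with those also found in another library in full colour and those in 1 library only in pale colour. The 12 h etoposide libraries hold 1886 and 1833, of which 1065 and 1040 recur elsewhere, and the others between 367 and 693.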

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

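The tests of coverage, recurrent junctions, treatment, random joining, fixation contacts and gene-body inversions were chosen after the results were seen, while the prediction for joining at an even rate was written before its value was known.

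Same-strand pairs within 20 kb, the orientation that a local inversion would give which the report counts only within totals of used or short-range pairs, made up 13.3% of pairs in Step 1 and 18.9% in Step 2, against 1.13% in Con and 0.696% in γH2AX-positive nuclei. The share also followed library type, being higher in the other libraries with more inward-facing pairs (2.00% in NeuN-positive γH2AX-negative nuclei, 3.32% and 4.54% in DMSO, 3.09% and 2.76% after 2 h) than in the 12 h cultures (0.887% and 0.723%), although none of them reached the Step libraries. Same-strand pairs had a median span of 977 bases in Step 1 and 1037 in Step 2. The gene-body ratio that follows cannot say how many of these pairs, if any, came from inversions. Inversions concentrated in gene bodies would put the gene-body ratio of same-strand to outward ends above that of γH2AX-negative nuclei, the other forebrain library of this type; they stay open, since against its 1.034 Step 1 lay higher at 1.039 (difference 0.00522, counting error 0.00459) and Step 2, at 1.035, did not by more than counting error (0.00114, 0.00455). Joining of nearby molecules at an even rate over the genome stays open: the spread between 1 Mb windows beyond counting was 0.203 log2 units in Step 1, just over the 0.2 set for it, and 0.166 in Step 2. What the labels Step 1 and Step 2 stand for is not defined and was not tested.

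Pairs 100 kb to 10 Mb apart were 2.89 times as frequent in Step 2 as in Step 1. Random joining of DNA ends would leave no excess, but the observed pairs were 12 times its expectation. Recurrent junctions in near-identical copies do not account for them either, since without those junctions the ratio was 3.76. Chromatin contacts kept by fixation and joined during preparation stay open: the excess fell with distance with a log-log slope of -1.21 (-1.23 to -1.20), the shallowest of all libraries, but 9 of the other 10 (-1.61 to -1.25) also lay in the range of -1.5 to -0.7 set for contacts, so the slope decides nothing. Rearrangements between neighbouring loci were not tested and stay open too, as does any difference that the labels Step 1 and Step 2 stand for.

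After 12 h of etoposide, 275 genes had fewer long-range ends than in DMSO and 252 had more, and the treatment cannot be told apart from library type, since 0 of the 12 h libraries are of the DMSO type. Short-range coverage stays open for the lower genes, whose median short-range log2 ratio was -2.22: with short-range ends as offset 0.364% were still called lower, but 80 were called higher and the median went from -1.40 past 0 to 0.80, so the offset took away more than the change. It stays open for the higher genes too: with the offset the median of the 180 testable went from 1.42 to 0.25 (quartiles -0.16 to 0.59), and 19 were still called higher, 10.6% of those but 7.54% of all 252, on either side of the 10% set. Pairs at recurrent junctions are not the whole cause in the 192 higher genes testable without them, where the median went from 1.51 to 1.41 (quartiles 1.00 to 1.91) and 127 were still called; the 65 that were not went from 1.37 to 1.05. Being testable favours genes with few ends at these junctions, since the other 60 had a median of 68.7% of their ends there. In those 60, with too few ends left to test, these junctions stay open. Their remaining ends gave a median log2 ratio of 1.49 (lower quartile 1.07) against 2.17 before. A lower quartile above 1.09 would have excluded these junctions.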

How the results depend on the processing

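Leaving out pairs at recurrent junctions was chosen after seeing the data, as were counting pairs within 10 bases once, the class of pairs 100 kb to 10 Mb apart and outward-facing pairs as denominator of forebrain shares. So were comparisons of forebrain libraries with a like pair orientation and division of forebrain gene ratios by short-range ratios. The other alternatives were planned. Over all alternatives, 222 values of comparisons were counted as staying, 76 moved and 5 turned direction. Staying meant within their spread or on their side of the threshold, except for culture shares and location ratios. For those it meant only that the direction held, however much the size changed. A further class held pairs 100 kb to 10 Mb apart, forebrain interchromosomal shares and the added forebrain comparisons. In that class, by the same rules, 67 values stayed, 54 moved and 3 turned. For named culture genes 1219 stayed, 283 lost their call and 19 turned, and for named forebrain genes 541 stayed and 19 moved. Where no cause is named below, the cause was not tested. Filters on mapping quality (30, 10 or none) were not run, since the files hold no such value. Depth was not varied. In counts simulated at this depth with a dispersion of 0.005, 2 of 67 genes changed 1.5-fold were recovered for 2 h of etoposide against DMSO. Of genes changed 4-fold, 46 of 66 were recovered.

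The ratio of γH2AX-positive to γH2AX-negative long-range shares (0.199) was 0.203 with duplicates kept, 0.2002 with no bins left out, 0.192 over 10 kb, 0.196 over 1 Mb and 0.196 without recurrent junctions. Step 1 over Con (0.631) was 0.618 with duplicates, 0.647 over 10 kb, 0.620 over 100 kb, 0.617 over 1 Mb and 0.627 without recurrent junctions. Step 2 over Con (0.607) was 0.595, 0.623, 0.590, 0.567 and 0.604 in that order. Step 2 over Step 1 (0.963) was 0.951 over 100 kb and 0.919 over 1 Mb. Over outward-facing pairs, which leaves out the inward-facing and same-strand pairs that differ between library types, the 4 ratios were 0.167, 0.844, 0.959 and 1.14, so that Step 2 over Step 1 turned; its interchromosomal ratio turned from 0.877 to 1.03. For pairs 100 kb to 10 Mb apart, Step 1 over Con turned from 0.951 to 1.04 without recurrent junctions (0.997 to 1.08, an interval that holds 1) and to 1.27 over outward-facing pairs. The number of recurrent junctions was 43544 at 2 pairs or more, since that admits single repeats.

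With each culture library left out in turn, the long-range difference ranged from -1.86 to 0.350 for 2 h against DMSO and from -2.08 to 0.129 for 12 h against DMSO, and the interchromosomal difference from -1.74 to 0.393 and from -2.02 to 0.116, turning without DMSO replicate 1. Genes called ranged from 20 to 769 (12 h against DMSO) and from 40 to 592 (12 h against 2 h), and windows from 184 to 1336 and from 2 to 1404. In the same order, coverage windows ranged from 0 to 2253 and from 2 to 2232, and from 0 to 2 for 2 h against DMSO, where the values were 1 and 2 without 12 h replicates 1 and 2. A group left with 1 library is assumed to vary like the others.

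Genes called for 12 h against DMSO (527) were 338 over 1 Mb, 350 without recurrent junctions, 204 with no filter on counts, which tests many more genes, and 866 with short-range ends as offset. For 12 h against 2 h (383) they were 243, 220, 111 and 947, and 252 with only these groups fitted, which leaves fewer libraries. Windows for 12 h against DMSO (640) were 414 under quantile normalization, and for 12 h against 2 h (666) 1136 with the offset. Coverage windows for 12 h against DMSO (47) were 1126 under quantile normalization, 1221 with limma-trend and 11 with only these groups fitted, and for 12 h against 2 h (113) 1095, 1418 and 2; for 2 h against DMSO the count was 1 with only these groups fitted.

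A replicate block treats equal replicate numbers as pairs, which the labels do not state. Between libraries of equal number, deviations of long-range ends per gene had correlations of -0.004, -0.071 and 0.067. Counting error weakens such correlations and coverage was not checked, so they do not exclude pairing. With the block, coverage windows were 427 for 12 h against DMSO and 1036 for 12 h against 2 h, and 1 window was called on long-range ends for 2 h against DMSO.

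With short-range ends as offset, which subtracts coverage that was lower in these genes, the log2 fold changes of 9 of the 15 named lower genes turned against DMSO and 10 of 15 against 2 h; the other 6 and 5 kept their direction and lost their call. Against DMSO those that turned were 0.84 for Itpr3, 0.15 for Myo15, 0.11 for Ssh1, 1.18 for Rbm19, 1.16 for Unc5b, 1.25 for Ccdc85c, 0.87 for Cbfa2t3, 0.33 for Smad3 and 0.95 for Triobp. Against 2 h they were 0.31 for Rap1gap, 0.45 for Rxra, 0.80 for Kdm4b, 1.11 for Tmem104, 0.029 for Fam53b, 1.24 for Rbm19, 0.97 for Flrt1, 1.13 for Unc5b, 0.81 for Cbfa2t3 and 0.38 for Myo15.

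Gene lists past the threshold (1 for 2 h against DMSO, 2 for each 12 h comparison) were 0, 0 and 0 with an estimated correlation. They were 1 for each 12 h comparison without members over 500 kb, which removes all 50 long neural genes and leaves that list untested, and 0 for 2 h against DMSO with the offset.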

Other observations

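The loci and junctions in this part were chosen after their values were seen.

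Smo, 2700054A10Rik and Gm20590 formed recurrent junctions with one another. The junction of Smo on chromosome 6 with 2700054A10Rik on chromosome 17 had 51 pairs in NeuN-positive γH2AX-negative nuclei, 42 in Step 1, 30 in Step 2, 5 in γH2AX-positive nuclei, 1 in Con and 16 over the 6 cultures. Scaled to long-range pairs, these were 38.9, 118, 102, 15.3, 2.91 and 10.2 CPM. The junction of Gm20590 on chromosome 13 with 2700054A10Rik had 52, 48, 62, 10, 3 and 17 pairs, or 39.7, 135, 211, 30.7, 8.72 and 10.8 CPM, in the same order. The first 3 libraries are of the library type with more inward-facing pairs and the next 2 of the other, and short-range ends in Smo were 5.71 times as many in Step 1 as in Con. Differences between these first 3 and next 2 libraries are therefore not separable from library type. The pooled cultures hold both types, so their values cannot be placed with either. Within Dock2, a junction between 34540001 and 34680001 on chromosome 11 had 48 pairs in Con and 0 in γH2AX-negative nuclei, whose library is of the other type.

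Cultures and forebrain also differed in their recurrent junctions: 188 were found in all 6 culture libraries and in no forebrain library, 12 in all 5 forebrain libraries and in no culture, and 64 in all 11. The labels do not give the mouse strain of the cultures, so a strain difference between cultures and forebrain was not tested and stays open. The same holds for a strain difference between the 12 h cultures and the DMSO and 2 h cultures. Within Igh, the junction of the bin with Gm18340 (chromosome 12, 115520001) and that with Gm18341 (115810001) had 61 and 51 pairs in the 12 h libraries, 3 and 6 in DMSO, 3 and 1 after 2 h, and 0 in the forebrain.

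The region at the lower-coordinate end of Camk2a (60925307 to 60988152), whose promoter drives the transgene system of CK-p25 mice, was joined to chromosome 12 in forebrain libraries alone. Ends between 60918021 and 60925592 on chromosome 18 paired with 115372273 to 115372323 in 7 pairs and with 116098193 to 116100488 in 8, of which 5 came from NeuN-positive γH2AX-negative nuclei, 1 from γH2AX-positive nuclei, 4 from Step 1 and 5 from Step 2. Con had 0, which allows up to 3, and its short-range coverage around Camk2a was 6.49 CPM of short-range pairs against 87.0 in Step 1. The cultures had 0 such pairs. No partner of Cdk5r1, the gene from which p25 derives, reached 3 pairs in any library.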
